A study of Mus musculus with 5 samples.

How the data were processed

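The samples are 5 mouse libraries made to map contacts between enhancers and promoters: 1 of embryonic stem cells (mESC, untreated) and 4 of bone marrow derived dendritic cells (BMDC, treatment given as LPS), all labelled SIP with an antibody to H3K4me3, a histone mark found at active promoters. Per the labels' protocols, nuclei of crosslinked cells were sonicated and digested with DNase to fragments of about 150 to 1000 bp, complexes were coupled to beads, and DNA ends were repaired and given a series of barcodes by repeated splitting and pooling. DNA fragments held in 1 complex pass through the same wells and so end with the same combination of tags. The dendritic cells were grown from marrow with GM-CSF and collected on day 8, and the protocol gives LPS at 100 ng/mL for 0, 4 or 24 h without saying which duration any of the 4 BMDC samples received. Libraries were amplified for 8 to 12 cycles. The submitters' processing notes name Bowtie2 2.3.1 and the mouse build mm10. Neither had any part in the values below, which come before alignment.

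The file deposited for each sample and analysed here is a barcode configuration list. It opens with 2 lines that state the order of tags in read 1 and read 2, and then gives, for each tag, its category, its name, its sequence and a whole number. Per the file headers, read 1 holds a DPM tag, and read 2 holds Y, ODD, EVEN and ODD tags with spacers between them. The fourth value of each entry carries no heading in the deposited lists, and was read as the number of mismatches allowed when a read is matched to the tag, because it takes only the values 0 and 2 and is the same for all tags of a category. These lists are inputs of the authors' barcode identification and not measurements of chromatin. Aligned reads, barcode clusters, contact maps and gene or region values were not analysed here, so sequencing depth is unknown and no gene, promoter or enhancer value is given. The parameters of the barcode matching program beyond these lists are not given in the sources used here. In 1 list, that of BMDC replicate 1, 387 lines ended in a carriage return, which was removed before reading.

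From the lists, 5 quantities were computed with Python 3.11.15 and NumPy 2.4.6. They were the tags in each category, the capacity (the product of the number of tags over the 5 tag positions), the share of tags that pairs of lists have in common (shared tags over tags in either list), the smallest Hamming distance between tags of equal length in a category, and tag lengths. A category whose smallest distance exceeds 2 times the allowed mismatches can be decoded without ambiguity for up to the allowed number of substitutions. With an allowance of 0, any category without repeated sequences meets this. The condition in each DPM name was read as the text after the tag number and, where present, the plate well. That reading was added after the lists were seen, because the names turned out to carry conditions. Wells were derived from tag numbers counted down the columns of a 96-well plate, a rule that held for 272 of the 272 entries that name a well, in 3 of the lists. The distance functions were tested on simulated data: a planted neighbour was recovered at its distance in 200 of 200 lists, and 0 of 40 lists of random bases were called non-random. The random lists held fewer tags than the deposited lists, at the length of ODD and EVEN tags. False calls were thus not checked at the DPM length, and no set selected for distance was simulated for that test.

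Groups were taken from the sample titles, with 1 mESC and 4 BMDC samples. Replicate numbers of the BMDC samples come from their titles, and nothing in the labels says whether they came from separate cultures or animals. A list is complete by construction and has no sampling error, so the SD given over BMDC samples describes how the lists differ. No test was made between cell types, since 1 sample against 4 cannot give an exact permutation p under 0.2. The rule for named items, fixed before the data were examined, was to name categories and totals, and single tags only if they occurred in 1 list alone or lay at or under 2 times the allowed mismatches from another tag, at most 6 in all. Tags named outside that rule are said to be so. The gene lists fixed at the same time had no values to be applied to. The alternatives were unique sequences only, capacity without the DPM or the Y position, sameness by name, by name with category and sequence, or on either strand, Levenshtein distance, distances over all categories of a read, lengths over all categories, and leaving out each BMDC sample in turn. Alternatives planned for measured values were not run. In the closing tests, 10000 sets of tags with the bases of each position shuffled among tags of equal length were drawn per category, and 100000 permutations were used for GC content.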

Results

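The study set out to map contacts among several enhancers and promoters at once in mouse embryonic stem cells and in dendritic cells grown from bone marrow and treated with LPS, an outer membrane component of Gram-negative bacteria that these cells sense through Toll-like receptor 4. The lists examined define the barcodes of 5 split-and-pool libraries, 1 of mESC and 4 of BMDC. Every list gave the same read structure, with a DPM adaptor tag in read 1 and a Y, an ODD, an EVEN and a second ODD tag in read 2, so that 5 tag positions identified a complex. The lists of mESC and of BMDC replicates 1, 3 and 4 held 384 tags each, and that of BMDC replicate 2 held 368. As the lists hold no reads, depth could not be assessed.

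The first comparison was of the conditions that each library named. The DPM names carried text that the sample labels lack, and by that text the 4 BMDC libraries were not 4 repeats of a single condition. The mESC library named mESC cells in all 96 of its DPM tags. BMDC replicate 4 divided its 96 DPM tags equally among 0h, 4h and 24h, with 32 tags each. BMDC replicate 3 named 4h in all 96 tags. BMDC replicate 2 named 0h in 40 tags and 24h in 40 tags, and held no tag named 4h. BMDC replicate 1 named 0h, 4h and 24h in 16 tags each, mESC in 40 tags and mDC24-SPRITE in 8 tags. SPRITE is the split-pool method that labels complexes without an antibody step, and the labels do not expand mDC24. The hours in the names match the 3 LPS durations in the protocol, but the names themselves do not mention LPS.

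**Figure D1:**
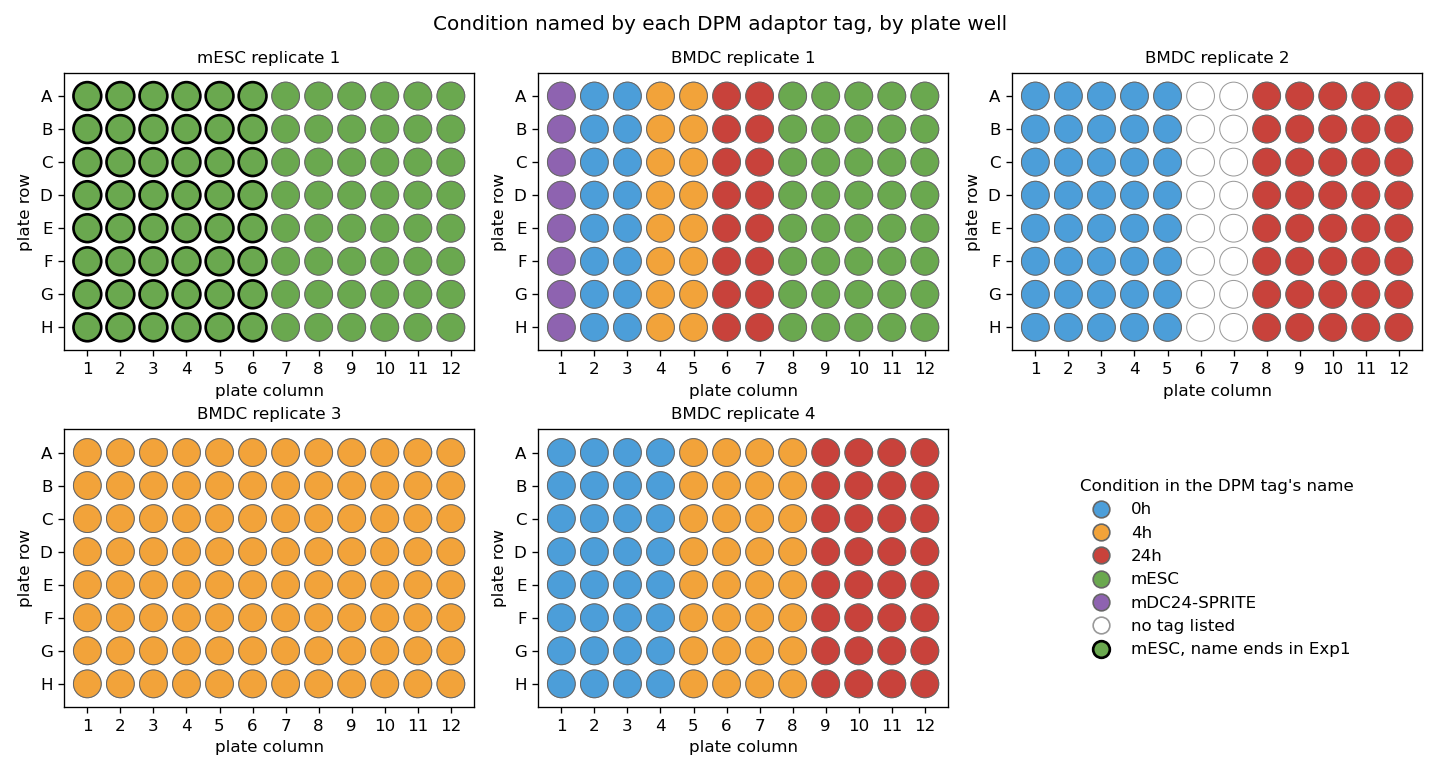
Each panel is the 96-well plate of DPM adaptor tags in 1 list (columns 1 to 12, rows A to H), with each well coloured by the condition in the name of its tag, and thick outlines marking names that end in Exp1. Wells were derived from tag numbers, as only 272 of the 464 DPM entries name a well. By these wells, conditions occupied whole plate columns. BMDC replicate 3 held only 4h tags, BMDC replicate 2 lacked columns 6 and 7, and BMDC replicate 1 gave columns 8 to 12 to mESC.

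Tags named by hour accounted for 320 of the 368 DPM entries of the BMDC lists (87.0%). The 48 others were the mESC and mDC24-SPRITE tags of BMDC replicate 1, which made up 50% of that list. Among the tags named by hour, only those of BMDC replicate 3 also held the text mDC. In BMDC replicates 1, 2 and 4 the hour names give no cell type, and dendritic cells were taken from the sample titles. Cells at 0h were represented by 88 tags over 3 BMDC libraries, or 29.3 ± 12.2 tags per library (SD, n = 3). Cells at 24h had the same total and spread, 88 tags and 29.3 ± 12.2 per library (SD, n = 3). Cells at 4h had 144 tags over 3 libraries, 48 ± 42.3 per library (SD, n = 3), and without BMDC replicate 3 their total was 48. The totals at 0h and at 24h each fell to 48 without replicate 2 and to 56 without replicate 4. BMDC replicates 1 and 4 held equal numbers at the 3 hours, 16 and 32 tags each. The higher 4h mean thus came from the 96 tags of replicate 3, against 40 at 0h and at 24h in replicate 2. Each mean leaves out the list without that hour, so the means cover different lists. The ranges overlapped, with 16 to 96 tags at 4h and 16 to 40 tags at 0h and at 24h. Embryonic stem cells had 136 tags, 96 in the mESC list and 40 in that of BMDC replicate 1. These totals count list entries and not distinct tags. The lists reuse the same DPM sequences, and a tag named for a condition in several lists is counted in each.

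The second comparison was of which conditions were named inside the same library. Complexes pooled in a library go through the later rounds of tagging together, and could be set against each other there. Whether the conditions named in a list were pooled and sequenced together was not tested, as it needs the reads. Cells at 0h and at 24h were named together in 3 BMDC libraries, replicates 1, 2 and 4. Cells at 4h were named with 0h in 2 libraries, replicates 1 and 4, and with 24h in the same 2. Embryonic stem cells were named with each of the 3 dendritic cell time points in 1 library, BMDC replicate 1. In the mESC list, 48 tags in plate columns 1 to 6 carried the text Exp1 and 48 in columns 7 to 12 carried Exp2. The text Exp2 also ended all 80 DPM names of BMDC replicate 2.

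With the mDC24-SPRITE tags kept apart, the tags named 0h and 24h held separate parts of the plate. Tags named 0h lay between DPM numbers 1 and 40 in every library that had them, and tags named 24h between 41 and 96, so that 0 DPM numbers were used for both. Counted as 24h, the mDC24-SPRITE tags (DPM numbers 1 to 8) would make this 8, as BMDC replicates 2 and 4 named these numbers 0h. The 3 libraries with 0h shared 16 DPM numbers for it, the 3 with 4h shared 8, and the 3 with 24h shared 0, although BMDC replicates 2 and 4 used 32 of the same numbers for 24h. No DPM number stood for the same condition in all BMDC lists, and over all 5 lists each stood for 3 or 4 conditions. The sequence behind a DPM number was identical in every list that held it.

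The third comparison was of the tags themselves between the mESC and BMDC libraries. The 288 ODD, EVEN and Y tags were identical in name and sequence in all 5 lists, and the 80 DPM sequences of BMDC replicate 2 occurred in all the others. The mESC list shared 99.0 ± 2.08% of its tag sequences with the BMDC lists (SD over 4 pairs, range 95.8% to 100%). The 6 pairs of BMDC lists shared 97.9 ± 2.28% (SD). Pairs reuse the same lists and are not independent. Every pair under 100% included BMDC replicate 2, so the means differ only by the share of pairs that hold this list. The mESC library listed 96 DPM tags and the BMDC libraries 92 ± 8 (SD, n = 4), a difference that came from the 80 tags of BMDC replicate 2 alone. With the other BMDC lists equal to the mESC list, this difference stays below the SD whatever replicate 2 holds. The SD therefore gives no evidence on whether the cell types differ.

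The number of tags sets how many complexes can carry distinct barcodes. With 96 tags at each of 5 positions the mESC library and BMDC replicates 1, 3 and 4 had 8153726976 possible combinations each, and BMDC replicate 2 had 6794772480. The BMDC mean was 7813988352 ± 679477248 (SD, n = 4), and it lay below the mESC value through BMDC replicate 2 alone. These are upper bounds from the lists and not numbers of complexes observed. Because a condition was fixed by its DPM tags, the combinations open to it followed its share of the plate, at 84934656 combinations per DPM tag. Cells at 4h had all 8153726976 combinations of BMDC replicate 3, 2717908992 in replicate 4 and 1358954496 in replicate 1. Cells at 0h and cells at 24h each had 3397386240 in replicate 2, and as many as the 4h cells in replicates 4 and 1. Embryonic stem cells had 8153726976 in their own library and 3397386240 in BMDC replicate 1.

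The last comparison was of how far apart the tags lay, which decides whether a sequencing error can move a fragment to another complex or another condition. DPM tags were 8 bases long, ODD and EVEN tags 15 bases, and Y tags 9, 10, 11 or 12 bases with 24 tags of each length. No mismatch was allowed in DPM and Y tags and 2 were allowed in ODD and EVEN tags. The smallest Hamming distance was 5 among ODD tags (3 of 4560 pairs) and 5 among EVEN tags (2 of 4560 pairs), above the 4 that would make a tag with 2 substitutions ambiguous. Between an ODD and an EVEN tag it was also 5. With insertions and deletions counted as well (Levenshtein distance), 4 ODD pairs and 1 EVEN pair lay at or under 4, the closest at 3. Mean distances were 10.9 ± 1.74 for ODD and 11.0 ± 1.75 for EVEN pairs (SD over pairs). DPM tags lay at least 3 substitutions apart, a distance reached by 7 pairs in every list, with a mean of 6.02 ± 1.15 over 4560 pairs in the full lists (SD). Of these 7 pairs, 5 joined tags of different conditions in BMDC replicate 1, 3 in replicate 2 and 2 in replicate 4, so that by substitutions alone 3 were needed in a DPM tag to move a read between conditions. By Levenshtein distance, tags of different conditions came as close as 2 in replicate 1 (4 pairs) and in replicate 4 (3 pairs), and 3 in replicate 2 (21 pairs). Among Y tags of equal length 1 of 1104 pairs lay 2 substitutions apart, NYBot51_Stg (CTCTGTTGTTGC) and NYBot52_Stg (CTCTGTTGTTTG). This pair falls outside the rule for named tags and was chosen after its values were seen.

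**Figure D2:**
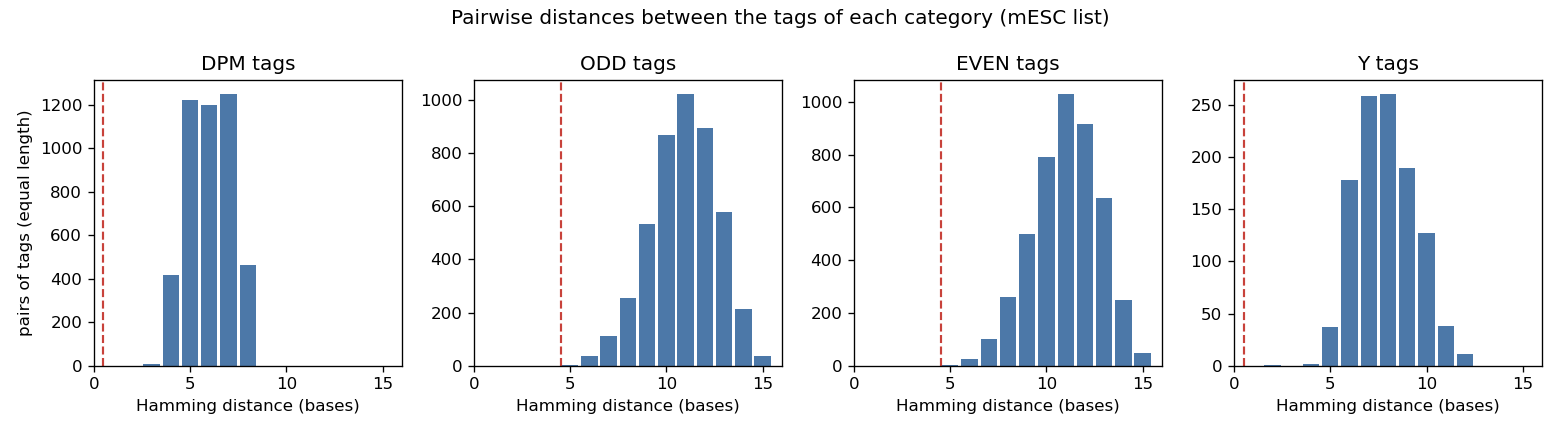
Number of tag pairs (vertical axis) at each Hamming distance in bases (horizontal axis) for the DPM, ODD, EVEN and Y tags of the mESC list, with pairs of equal length only and a separate vertical scale per panel. The dashed line stands just above 2 times the allowed mismatches (0 for DPM and Y, 4 for ODD and EVEN). All pairs lie to its right, from 3 bases for DPM, 5 for ODD and EVEN, and 2 for Y. For DPM and Y this would hold for any list without repeated sequences.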

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

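The test of the missing DPM tags and that of the mESC names in this part were chosen after the lists had been seen, and no biological explanation was tested for either pattern, since the sample groups name none.

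BMDC replicate 2 listed 80 DPM tags where the other 3 BMDC lists held 96, and stood apart from them by the whole range of the 4 values; with 3 equal values any departure is flagged. The 16 absent tags were DPM numbers 41 to 56, all wells of plate columns 6 and 7, between the 0h and the 24h blocks. A list broken off at its end is argued against, because 0 of the 16 absent tags would have stood among the last 16 in the alphabetical order that this list uses. Whether the wells were empty or held complexes that the list leaves out was not tested, as it needs the reads.

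BMDC replicate 1 listed 40 DPM tags named mESC and 8 named mDC24-SPRITE, neither of which its sample labels mention. Entries carried over word for word from the mESC library's list are argued against: 0 of the 40 names occur there, where names also hold a well and Exp1 or Exp2. The names differ in format throughout, so entries copied and then renamed stay open. Whether the list belongs to another library that also mixed conditions was not tested. It also stays open whether mESC complexes were sequenced in this library or only named in its list, which the reads behind these 40 tags would show.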

How the results depend on the processing

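Of 86 recomputed values for 20 results, 66 stayed the same by the criteria used (within 1.5 times for counts, within 1 SD between lists otherwise) and 20 moved. Unique sequences changed nothing, as no list repeats a sequence. Leaving out a BMDC list could not move the ODD, EVEN and Y counts or any smallest distance, which are the same in every list. Leaving out a list that lacks a condition could not move the total of that condition. The count of 66 is therefore no measure of robustness. Leaving out either the DPM or the Y position lowered the mESC capacity to 84934656 combinations; for the BMDC mean the values were 84934656 without DPM and 81395712 without Y. Counting only BMDC tags named SIP_me3 with 0h, 4h or 24h, an alternative chosen after seeing the data, gave a mean capacity of 6794772480. Matching tags by name, alone or with category and sequence, lowered the share common to mESC and BMDC to 60.5%, as no DPM name of the mESC list occurs in a BMDC list. With insertions and deletions counted (Levenshtein distance) the smallest distance was 2 for DPM, 3 for ODD and 4 for EVEN, and stayed at 2 for Y. An allowance of 2 that also covered insertions and deletions would not separate every ODD and EVEN pair. Whether the matching program counts them is not known here. By Levenshtein distance the closest ODD tags were Odd2Bo58 (CGTTCCATGCTATCT) and Odd2Bo82 (CCTTCCTATGCTACT). By Hamming distance other ODD pairs were closest, and this pair falls outside the rule for named tags. Over all categories the mean tag length was 12.1 bases. Leaving out each BMDC list in turn, also added after seeing the data, gave 48 to 88 tags named 0h, 48 to 144 named 4h and 48 to 88 named 24h; the lowest values came without replicate 2 (0h and 24h) and without replicate 3 (4h), and without replicate 4 the 0h and 24h totals were 56. Counting the mDC24-SPRITE tags as 24h, another alternative added after seeing the data, raised the 24h total to 96 and the DPM numbers named both 0h and 24h from 0 to 8; no list left out changed that 0. The alternatives planned for measured values were not run, since the lists hold none. Depth sets no limit on a list, and what it limits in the contacts is unknown here.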

Other observations

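The tests of tag spacing below were chosen after the distances had been seen, and the test of GC content was stated before its result was computed. By their tag names BMDC replicates 1, 2 and 4 each held 2 or 3 of the hours 0h, 4h and 24h, and BMDC replicate 3 held 4h alone; that these hours are LPS durations was not tested.

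The closest DPM tags lay farther apart than the closest tags of sets with the same base composition at each position; mean distances were not compared, as the shuffling leaves them unchanged. The smallest DPM distance of 3 was reached in 0 of 10000 shuffled sets, whose median was 1 and maximum 2, giving a one-sided permutation p of 0.0001, the smallest these draws can give (adjusted p = 0.0004 over 4 categories). The other categories gave no such result. A smallest distance of 5 or more arose in 3500 of the 10000 shuffled ODD sets (permutation p = 0.3501, adjusted 0.5355) and 4015 of the shuffled EVEN sets (p = 0.4016, adjusted 0.5355), with a median of 4 in both. For Y tags a distance of 2 or more arose in 9718 of the shuffled sets (permutation p = 0.9718, adjusted 0.9718), whose median of 3 exceeded the observed value. The Y result rests on 1 pair, as the next closest Y pairs lay at 4. That was also the largest smallest distance of any shuffled Y set. A hypothesis is that DPM tags were selected for distance. Bases drawn at random could account for the smallest distance within the ODD, the EVEN and the Y tags, for Y through 1 pair. That ODD, EVEN and Y tags were selected, perhaps less strictly, stays equally open. ODD and EVEN tags were shuffled apart, so the smallest distance of 5 between an ODD and an EVEN tag was not tested. The lists allow 0 mismatches for DPM and Y and 2 for ODD and EVEN, so the allowances do not divide DPM from the other categories.

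With the mDC24-SPRITE tags kept apart, 0h and 24h shared no DPM tag (8 if these are counted as 24h), so that a bias tied to the tags would be largely confounded with these 2 hours, and GC content was tested as 1 such property. DPM tags ranged from 0% GC (DPM5bot32, TTTTATAA, outside the rule for named tags and chosen after its value was seen) to 87.5% GC (3 tags). Conditions within a library nevertheless had close means, with differences between the highest and the lowest of 3.12 percentage points in BMDC replicate 1, 1.25 in replicate 2 and 1.95 in replicate 4. Permutation of tags among conditions gave p of 0.984, 0.802 and 0.910. The mESC list holds 1 condition, and there the Exp1 and Exp2 tags were compared instead, with means 1.04 percentage points apart (permutation p = 0.818). The adjusted p was 0.984 for each of the 4 lists. These lists draw on the same DPM sequences, so the 4 tests are not independent. As a list is complete, the differences in means are exact, and p only sets them against random assignment of tags. Mean GC was higher at 0h than at 24h in each BMDC list that held both. The means were 53.1% against 50% in replicate 1, 51.6% against 50.3% in replicate 2 and 51.2% against 49.6% in replicate 4. The 3 BMDC ranges lay under the bound of 10 percentage points set beforehand. This argues against a large difference in mean GC between conditions, as the mESC value does between Exp1 and Exp2. The spread of GC within conditions and other properties of the tags and of plate position were not tested.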
